A study of Arabidopsis thaliana with 3 samples.

How the data were processed

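The series holds 3 two-colour oligonucleotide arrays of rosette leaves from 5-week-old Arabidopsis thaliana plants of the Col-0 ecotype, per the labels. Each array set RNA of a transgenic line called AhNF-YC-OE, in the Cy5 channel, against RNA of wild type, in the Cy3 channel. There was 1 array for each condition: normal growth, water stress for 5 days, and recovery. Leaves of the recovery array were taken 24 h after rewatering of plants stressed for 8 days, per the labels of that sample; the protocol text of the other samples names 5 days only. Plants grew at 22 °C with 16 h of light and 8 h of darkness, per the labels. RNA was extracted with Trizol, purified with LiCl and copied into fluorescent cDNA, per the labels' protocols. The label fields name the dyes Cy3 and Cy5 and the labelling protocol names Alexa dyes. No array had the dyes exchanged, so a dye bias of a probe and a genotype difference both enter each ratio.

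The scanner values are the mean pixel intensity of each spot and of its local background in both channels, with the SD of the background pixels, per the file headers. The scanner, its settings and the quantification software are not given in the sources used here. Each array has 30000 spots in 48 blocks of 25 by 25. The authors also deposited a normalized intensity for each channel and its log2 ratio of AhNF-YC-OE over wild type, with 27474, 27475 and 27427 entries for normal growth, water stress and recovery. The method of that normalization is not given in the sources used here. A deposited table of the series holds 1 log2 value per feature number and array, with medians of −0.0066, 0.0071 and 0.0040. In each array, at least 99.4% of the deposited log2 ratios recur in that table, which settles its direction and its log base. How the authors scaled and centred the values stays unknown.

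Gene identities are those of the array annotation, which uses locus codes of TAIR release 7 and TIGR release 5, per the file headers. A RefSeq table of assembly GCF_000001735.4 (TAIR10.1) gave names only, and 25818 of the 26017 loci were found in it. Of 7411 library spots with a symbol in the deposited annotation, 98.6% carried a symbol or synonym that the table lists for the locus. There is no probe for the transgene among the annotated features.

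The analysis began from the scanner intensities. Background was corrected with normexp at an offset of 50, and ratios were normalized by loess over intensity within each array, with control and empty spots at weight 0 (limma 3.58.1 in R 4.3.3). Spots of a probe were averaged, and a locus with several probes was represented by the brightest. A gene entered the counts of an array when its brighter channel lay above the local background mean plus 2 SD. Comparisons between arrays of one genotype used single-channel log2 intensities after Aquantile normalization. Tables and lists were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A gene not above background in the dimmer channel is given as a bound, written "at least", with the dimmer channel set to its background limit.

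With 1 array per condition there is no spread between plants, and the number of arrays limits the precision of every value. No gene was tested for a difference and no p-value is given; places among random lists and intervals over spots describe these arrays and do not cover the spread between plants. The mean genotype ratio over the 3 arrays was not tested, since the conditions differ and a dye bias of a probe would enter each array alike. Genes were counted when the log2 value was at least 1 in size, which is 2-fold. Comparisons, alternatives, gene lists and the rule for named genes were fixed before the data were examined. There were 10 comparisons: the genotype ratio on each array, its overlap over all 3 arrays, the difference of the ratio between water stress or recovery and normal growth, and, within each genotype, water stress over normal growth and recovery over water stress. For 23 gene lists and 2 lists made from words of the annotation (25 in all), the median log2 value was placed among 10000 random lists of the same size matched on intensity in 20 bins. A list with fewer than 5 measured members has single values only. Positions below 2.5 or above 97.5 percent are called outside. In each comparison, 24 lists had a position, and 1.2 would fall outside by chance.

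Named genes followed this rule. Among genes above background whose probes all had 1 sign, it took the 8 highest and 8 lowest ratios of each array that were also at least 1.5-fold the same way without background correction, and per array and list up to 4 members at least 2-fold apart. It also took every NF-YC gene, genes 2-fold apart on all 3 arrays, the 6 highest and 6 lowest differences of ratios and single-channel changes, and 8 drought genes whatever their value. Genes without a name could be passed over for the next in rank. The genes RCA and GRP8, and list members given as examples of the single-channel changes and of the phosphate list, were chosen after their values were seen.

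The loess step and the 2-fold call were tested on simulated data, with 50 spots changed at each size and 29034 unchanged. Background correction, the filter on dim genes and the averaging of spots were not simulated. The noise was equal for all spots, at the SD between spots that share an annotation. It was 0.205, 0.288 and 0.197 in the order of the arrays, close to the SD over all gene spots of 0.217, 0.303 and 0.222. At a simulated log2 size of 1.5, the percentage called was 100.0 for normal growth, 96.0 for water stress and 100.0 for recovery. At a size of 1, at the threshold itself, it was 50.0, 52.0 and 38.0. Unchanged spots called numbered 0, 18 and 0. The simulation held no slide pattern and no shift of dim spots left after loess. These numbers therefore do not give the rate of false calls on the real arrays.

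The alternatives were no background correction, plain subtraction, median centring, loess within print-tip blocks, the authors' normalized values, 3 other filters on dim genes (none, both channels, and intensity above the array median), the mean of the probes, the first or the last spot of each probe, and a call at 2 SD in a sliding window of 501 genes over intensity. Median centring shifts each array by 1 value without loess, so any trend of the ratio over intensity stays in it. Quantile normalization of all 6 channels and median scaling of each channel were tried for the comparisons between arrays. An alternative that keeps only genes brighter in at least 1 channel than 95% of the spots annotated as empty was chosen after seeing the data. That filter was stricter on the normal growth array, where 46.1% of gene spots passed it, against 85.1% under water stress and 86.9% in recovery. The rescaled net intensity columns of the deposited scanner tables were not used here.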

Results

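The data compare rosette leaves of a transgenic Arabidopsis line, AhNF-YC-OE, with wild type in 3 states: normal growth, 5 days of water stress, and recovery 24 h after rewatering. The name of the line points to an NF-YC subunit, part of the trimeric CCAAT-binding transcription factor NF-Y, kept at a high level. Each state has 1 two-colour array with both genotypes on it, so no difference here has a replicate check. The arrays carry 29234 spots annotated to genes, for 26017 loci. The median spot intensity of these was 4208 in wild type and 3042 in AhNF-YC-OE on the normal growth array. It was 1422 and 812 on the water stress array, and 1399 and 962 on the recovery array. Median signal over background ranged from 14.9, in AhNF-YC-OE under water stress, to 85.9, in wild type under normal growth. At least 99.9% of gene spots lay above local background in the brighter channel on each array, as did 92.0%, 92.5% and 86.7% of 510 spots annotated as empty.

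A gene name in this text is the name that the array annotation gives to a spot, and spots given the same name shared little of their signal level. Across 1201 pairs of spots annotated to one transcript, the correlation of levels was 0.042, 0.049 and 0.074 on the normal growth, water stress and recovery arrays. The upper end of the middle 95% of 1000 random pairings was 0.052, 0.052 and 0.060. The log2 ratios of the same pairs correlated at 0.119, 0.129 and 0.191, above the corresponding ends of 0.0546, 0.0567 and 0.0522. Random pairings do not keep the place of the spots on the slide. The log2 ratios of 3993 pairs of one locus on one plate correlated at 0.177, 0.135 and 0.182. Shuffles of the printing rounds of those plates came close, with highest values of 0.163, 0.129 and 0.177. These correlations are across spots of one array, which are not independent replicates. Spots annotated to nuclear photosynthesis genes, which a leaf expresses strongly, lay at the 51.4th, 57.3th and 50.4th percentile of library gene spots by their median. The 4 spots annotated to RCA, the activase of Rubisco, spread from the 13.4th to the 80.3th percentile under normal growth. All 5 spots annotated to GRP8, a glycine-rich RNA-binding protein, lay at or above the 98.1th percentile there. Control features with at least 8 spots were more uniform: differences between these 33 features held 0.952, 0.950 and 0.916 of the variance of their 380 levels.

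**Figure D1:**
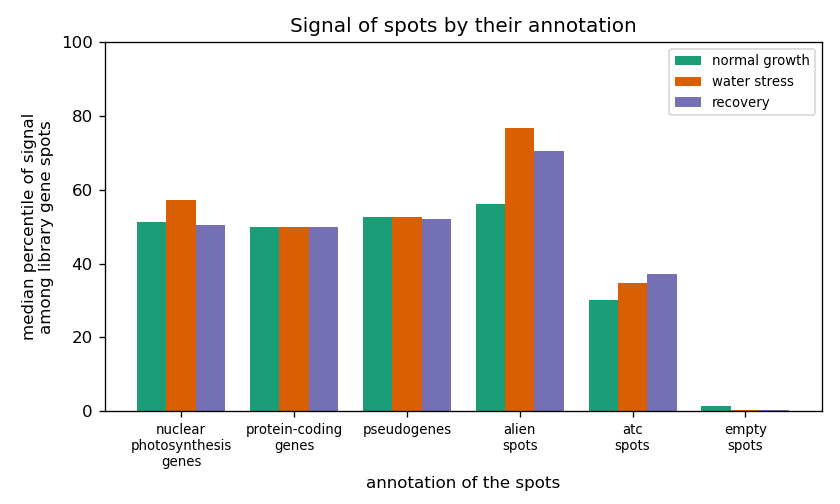
Median percentile of signal among library gene spots (vertical axis, 0 to 100) for spots grouped by their annotation (horizontal axis), with 1 bar per array. Photosynthesis genes lie at 51.4, 57.3 and 50.4, pseudogenes at 52.8, 52.5 and 52.0, alien control spots at 56.2, 76.8 and 70.7, and empty spots at 1.24, 0.144 and 0.144.

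Under normal growth few genes lay 2-fold apart between genotypes, and this comparison asks what the transgene changes without stress. Of 26009 genes, 24 were at least 2-fold higher and 2 at least 2-fold lower in AhNF-YC-OE, and 98.2% lay within 1.5-fold. The highest named genes were RABA1i, a Rab GTPase, at a log2 ratio of 1.39, PRP40A, a pre-mRNA processing protein, at 1.28, and LLG1, a GPI-anchored partner of receptor kinases, at 1.23. The lowest was RHA1A, a RING-H2 finger protein, at −2.14. The other gene below the threshold, AT1G33700, has no name in the table used and stood at −2.11.

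Among the further high genes were an aquaporin of the plasma membrane, PIP1;5, at 1.18, and one of the TIP family, TIP5;1, at 1.03. LSH5 stood at 1.15, the kinesin ATK5 at 1.13 and NHL8 at 1.07. PIP1;5 was the only member of a fixed list at least 2-fold apart on this array, as 1 of 17 aquaporin genes, and in the authors' values it was 0.98. LSH5, NHL8 and TIP5;1 also lay below the threshold in the authors' values, at 0.94, 0.85 and 0.91, and ATK5 did after median centring, at 0.997. After RHA1A the lowest named genes did not reach 2-fold. They were the MAP kinase MPK9 at −0.96, the auxin synthesis gene YUC9 at −0.83, the nuclear import receptor TRN1 at −0.83, and PnsB3, a subunit of the chloroplast NAD(P)H dehydrogenase complex, at −0.80. CHI, a chitinase, stood at −0.77, SMP1 at −0.75 and the response regulator ARR3 at −0.72. The authors' normalized values gave 14 genes higher and 11 lower, plain background subtraction gave 41 and 16, and median centring gave 428 and 2.

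The endogenous NF-YC genes, relatives of the transgene, were all within 2-fold between genotypes on the 3 arrays. NF-YC10 had the largest ratios, 0.86 under normal growth, 0.40 under water stress and 0.34 in recovery, and with median centring it reached 1.12 and 1.23 on the first and the second of these. NF-YC4 stood at 0.30, 0.22 and 0.18 in the same order, with −0.14 under water stress after median centring. NF-YC6 stood at −0.51, −0.08 and −0.05, and median centring turned these to 0.28, 0.75 and 0.45. NF-YC2 stood at 0.14, −0.25 and −0.49, with 0.06 under water stress after print-tip loess and 0.18 in the authors' values. NF-YC3 stood at 0.22, −0.06 and −0.32, and the second of these was 0.01 after median centring. NF-YC5 stood at 0.05, 0.33 and 0.19, with −0.07 after median centring under normal growth and −0.01 after print-tip loess in recovery. NF-YC1 stood at 0.18, 0.04 and 0.03, and median centring gave 1.07 under water stress while print-tip loess gave −0.01 there. NF-YC7 stood at −0.02, −0.28 and 0.09, with −1.23 under water stress and −0.30 in recovery after median centring. NF-YC8 and NF-YC9 lay between −0.11 and 0.10, and their signs changed with the scaling. No endogenous member gives the level of the transgene, for which the annotation holds no probe.

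Under water stress the array had more genes past the threshold, 128 higher and 88 lower in AhNF-YC-OE of 26011. This comparison asks how the genotypes differ under drought, and a genotype difference that is there without stress also enters it. Among genes with a name, the lower group was led by RHA1A at −1.83, the cyclin CYCB3;1 at −1.41 and RSH2, a root hair gene of the MATE transporter type (AT1G12950), at −1.34. The higher group was led by dim spots, among them the cytochrome P450 genes CYP714A2 at 1.94 and CYP71A14 at 1.93. The spots annotated as empty had a median log2 ratio of 1.76 on this array, and 90.8% of them were at least 2-fold higher. Only 3 of the 128 higher genes, but all 88 lower ones, were brighter than 95% of empty spots in at least 1 channel.

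Other named genes of the lower group were SHY2, a repressor of auxin responses, at −1.24, and the SIN3-like corepressors SNL4 at −1.23 and SNL3 at −1.21. DRL1, a partner of the Elongator complex, stood at −1.21 and QKY at −1.18. With loess within print-tip blocks RHA1A, at −1.86, and CYCB3;1, at −1.03, stayed past the threshold. RSH2 fell short of it at −0.95, SHY2 at −0.80, SNL4 at −0.99, SNL3 at −0.79, DRL1 at −0.74 and QKY at −0.71. Named genes of the higher group, none of them brighter than 95% of empty spots, included CAD1, a regulator of cell death, at 1.91, and CYP71B13, at 1.88. ORTHL, a ubiquitin ligase, stood at 1.82, CDR1, an aspartic protease of disease resistance, at 1.77, and OVA2, an isoleucyl-tRNA synthetase, at 1.76. SERPIN1, a protease inhibitor, was at least 1.76, with the opposite sign, −0.17, in the authors' values. After median centring all of these higher genes lay below the threshold, CYP714A2 at 0.80 and OVA2 at 0.62. Print-tip loess lowered CYP714A2 to 0.35, CYP71A14 to 0.20, CAD1 to 0.60 and CYP71B13 to 0.15.

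The split between higher and lower genes under water stress depended on the scaling. Median centring gave 1862 higher and 3577 lower, plain subtraction 332 and 391, and the authors' values 140 and 243. Among genes above the median intensity of the array, 0 were higher and 2 lower.

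In recovery most genes past the threshold were lower in AhNF-YC-OE, 100 against 14 higher, of 26006. The lowest was AT1G02660, at −2.43, followed by RHA1A at −1.95, RSH2 at −1.85 and HYL1, a microRNA processing protein, at −1.72. LAS, a GRAS regulator of axillary meristems, stood at −1.43 and MYB110 at −1.41. PRK, the phosphoribulokinase of the Calvin cycle, stood at −1.36, and PPa1, a soluble pyrophosphatase, at −1.34. Among genes with a name, the highest was SIP1, a seed imbibition protein, at 1.12.

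PEN3 (AT5G36150), a triterpene synthase, stood at −1.35. With loess within print-tip blocks LAS was −0.93, PRK −0.87 and PEN3 −0.86, below 2-fold, whereas HYL1 stayed at −1.44, and PRK was −0.99 in the authors' values. From the fixed lists, PETE2, a plastocyanin, stood at −1.05 and HTR12, the centromeric histone, at −1.11, the latter at −0.75 after print-tip loess. In the higher group S6K2, a ribosomal S6 kinase, was at least 1.04, and ASP1, an aspartate aminotransferase, at least 1.05. The serine carboxypeptidase scpl38 stood at 1.04. CYP71B13 and the triterpene synthase CAMS1 were both at least 1.01, while GME, which acts in ascorbate synthesis, was at least 0.998 and CAD1 at least 0.985. After median centring all of these higher genes lay below the threshold, SIP1 at 0.61 and scpl38 at 0.53. The empty spots had a median log2 ratio of 0.95 on this array, and 29.6% of them were at least 2-fold higher. Of the genes brighter than 95% of empty spots, 1 was higher and 100 were lower. Print-tip loess gave 27 higher and 53 lower, median centring 155 and 385, plain subtraction 124 and 331, the authors' values 58 and 193, and genes above the median intensity 0 and 1.

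The lower genes of the water stress and recovery arrays were mostly annotated to chromosome 1. They numbered 67 of 88 under water stress (76.1%) and 74 of 100 in recovery (74.0%), while 25.8% of all tested genes are on chromosome 1. Of the 128 higher genes under water stress, 22 (17.2%) were on chromosome 1. The library is printed largely in chromosome order, with the median spot of chromosome 1 in row 4 of its block and that of chromosome 5 in row 22. Among chromosome 1 spots of recovery, 2.05% were lower in block rows 1 to 4 of the slide, 0.438% in block rows 5 to 8 and 0.996% in block rows 9 to 12. For the other chromosomes the shares were 0.263%, 0.0424% and 0.141%. Within blocks, the share in recovery was 1.61% in rows 1 to 3 and 0.819% in rows 4 to 6, both of chromosome 1, and 0.0850% in rows 8 to 10, of chromosome 2. Under water stress the shares were 1.19%, 0.847% and 0.0283% in the same order. SHY2, SNL3, SNL4, DRL1, QKY, CYCB3;1, RSH2, HYL1, LAS, PRK, PPa1, PETE2 and HTR12 are all among the chromosome 1 loci, whereas RHA1A, MYB110 and PEN3 are not.

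**Figure D2:**
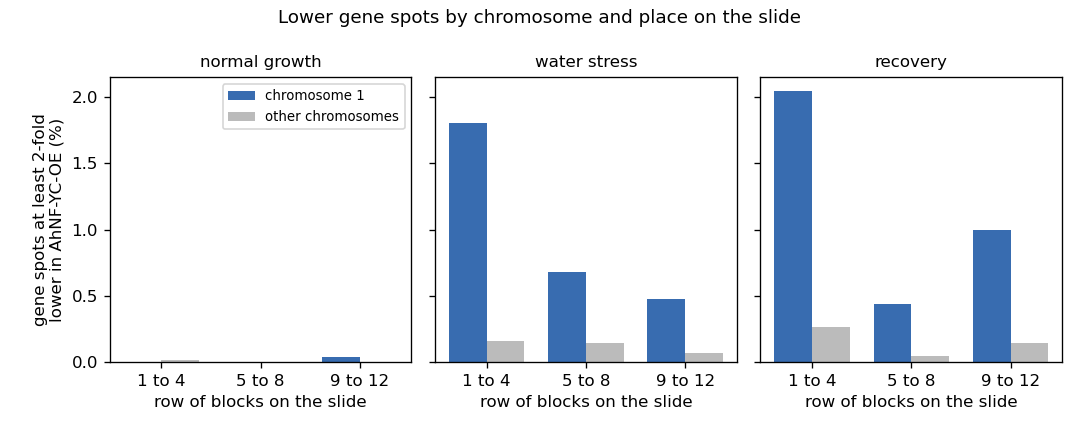
Percentage of gene spots at least 2-fold lower in AhNF-YC-OE (vertical axis) by rows of blocks on the slide (horizontal axis), for chromosome 1 and the other chromosomes, with 1 panel per array. In recovery, chromosome 1 spots were lower in 2.05%, 0.438% and 0.996% of cases from the first to the last group of block rows, and under water stress in 1.80%, 0.676% and 0.478%.

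Over all 3 arrays, 1 gene was at least 2-fold lower on each and 1 was higher. RHA1A was lower throughout, at −2.14, −1.83 and −1.95, and stayed past the threshold with median centring, print-tip loess, plain subtraction and the authors' values. It was brighter than 95% of empty spots under water stress and in recovery but not under normal growth, and below the median intensity on all 3 arrays. AT5G25400 was higher, at 1.02, 2.07 and 1.14, with 0.95 and 0.68 under water stress and in recovery after median centring. RHA1A and AT5G25400 have 1 spot each, and a dye bias of a spot would enter each array alike. Water stress and recovery shared 11 higher and 18 lower genes, where independent lists would share 0.0689 and 0.339. Independent lists are no reference for the absence of a genotype effect, since both arrays share the layout and the dye direction. Empty spots were high on both, with median log2 ratios of 1.76 and 0.95. Only 3 of the 128 higher genes under water stress and 1 of the 14 in recovery were brighter than 95% of empty spots. Among the shared lower genes were RSH2, CYCB3;1 and LAS, and the shared higher genes included ASP1, scpl38 and CYP71B13. No gene past the threshold on one array was past it the other way on another.

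Across 25997 genes, which are not independent replicates, the ratios of water stress and recovery correlated with r of 0.671 (Spearman 0.656). The correlation was 0.238 between normal growth and water stress (Spearman 0.255) and 0.298 between normal growth and recovery (Spearman 0.316).

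**Figure D3:**
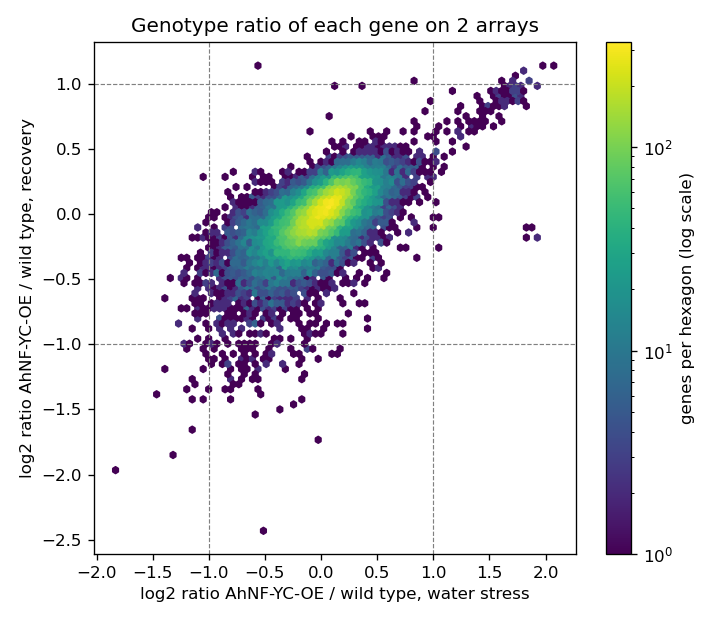
Log2 ratio of AhNF-YC-OE over wild type of each gene under water stress (horizontal axis) and in recovery (vertical axis), as the number of genes per hexagon on a log colour scale, with dashed lines at 2-fold. The correlation across genes is 0.671, and RHA1A lies at −1.83 and −1.95.

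The difference of the genotype ratio between states asks which genotype effects depend on water supply. With 1 array per state, water supply and array differ together in it. A dye bias that is constant cancels, and one that changes between arrays does not. Empty spots had median log2 ratios of 0.25, 1.76 and 0.95 in the order of the arrays, so the ratio of the dimmest spots was not constant. Between water stress and normal growth 116 genes differed upward and 92 downward by at least 2-fold. AT1G33700 rose most, by 2.18, since it was low under normal growth only. Named genes after it were CYP71A14 at 1.90, the cyclin CYCT1;1 at 1.80, ASP1, at least 1.73, DAF1 at 1.68, OVA2 at 1.66 and scpl38 at 1.64. All of these named genes lay below the threshold after median centring, CYP71A14 at 0.89 and scpl38 at 0.45. In the authors' values DAF1 was −0.60 and scpl38 −0.12, the opposite sign, and CYCT1;1 was 0.06. The named genes that fell most were RALFL17, a signalling peptide, at −1.32, the ADP/ATP carrier AAC3 at −1.30, Tic20-V of the chloroplast import channel at −1.26, the autophagy gene ATG18H at −1.22, RABA1i at −1.21 and the cyclin CYCD6;1 at −1.18. RALFL17 was −0.76 and AAC3 −0.86 after median centring, and CYCD6;1 was −0.92 after print-tip loess. Of genes brighter than 95% of empty spots, 2 differed upward and 31 downward, and among genes above the median intensity 0 and 34. Median centring gave 11 and 2947, and the authors' values 159 and 223.

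Between recovery and normal growth 7 genes differed upward and 79 downward. AT1G02660, without a name in the table used, fell most, by 2.59. Among genes with a name, RSH2 fell by 1.65, then RABA1i by 1.45, PETE2 by 1.43, the cytokinin response factor CRF2 by 1.41, HYL1 by 1.38 and PPa1 by 1.31. Upward, the genes with a name were CAMS1, at least 1.15, ASP1, at least 1.06, scpl38 at 1.07, CYCT1;1, at least 1.04, DAF1 at 1.00 and SIP1 at 0.96, the last at −0.20 after median centring. CAMS1, ASP1, scpl38, CYCT1;1 and DAF1 lay between 0.51 and 0.79 after median centring. The numbers up and down were 114 and 295 with plain subtraction, 15 and 46 with print-tip loess, 51 and 179 in the authors' values and 1 and 305 with median centring. Among genes brighter than 95% of empty spots they were 1 and 17, and above the median intensity 0 and 13.

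Water stress over normal growth within each genotype compares 1 array with another, so drought and array differ together. COR47 and ERD10, dehydrins, and ANAC055, a stress transcription factor, were higher in both genotypes. COR47 rose by 2.69 in wild type and 2.57 in AhNF-YC-OE, ERD10 by 2.12 and 2.06, and ANAC055 by 2.87 and 2.86. ERD6, a sugar transporter, and ANAC019 of the same family as ANAC055, were lower, at −2.60 and −1.51 in wild type and at −2.18 and −1.43 in AhNF-YC-OE, with ANAC019 at −0.45 and −0.38 after median scaling. Of the 38 measured drought and ABA-responsive genes, 11 were at least 2-fold higher and 4 lower in wild type, and 7 and 2 in AhNF-YC-OE. The list median was 0.38 in wild type and 0.24 in AhNF-YC-OE, at the 94.7th and 90.0th percentile of random lists, within the middle range.

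Among the 8 drought genes fixed in advance, LTI30, a dehydrin, was past the threshold, at 1.19 in wild type and 1.32 in AhNF-YC-OE, with 0.96 in wild type after median centring. RD29B stood at 0.57 and 0.77, RD29A at 0.44 and 0.43, and the dehydrin RAB18 at 0.35 and 0.46. RD29A was 1.95 and 1.92, and RAB18 1.59 and 1.68, with median scaling of each channel. NCED3, which makes the ABA precursor, stood at 0.54 and 0.11. RD20, a caleosin, stood at 0.09 and 0.18, with −0.15 in wild type after median centring and 1.43 and 1.51 with median scaling. P5CS1, of proline synthesis, stood at −0.18 and −0.13, and median scaling turned these to 0.49 and 0.52. ERD5, a proline dehydrogenase, stood at −0.57 and −0.35, with 0.17 in AhNF-YC-OE after median scaling.

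In all, 3981 genes were at least 2-fold higher and 3923 lower under water stress in wild type, and 3332 and 3404 in AhNF-YC-OE. The highest named genes were GLY2, a glyoxalase, at 4.28 in wild type and 4.08 in AhNF-YC-OE, the amine oxidase AO1 at 4.17 and 3.97, and SK10, an SKP1-like protein, at 3.94 and 3.99. In wild type CPUORF7 at 3.96, LLG1 at 3.88 and NCRK at 3.85 followed, and in AhNF-YC-OE SDG4 at 3.72, WRKY25 at 3.71 and PSB29 at 3.67. The lowest named genes in both were the calcium-dependent kinase CDPK1, at −6.48 and −5.46, and the myosin XIB, at −5.30 and −5.09. CYP71B9 stood at −4.94 and −4.52, and NUDT17 at −4.93 and −4.51. In wild type CYCT1;1 at −5.29 and NUDX26 at −5.03 were as low, and in AhNF-YC-OE TIF3H1 at −5.21 and CSLD5 at −4.70. Among NF-YC genes, NF-YC3 was lower at −2.41 and −2.69, NF-YC4 higher at 1.40 and 1.32, and NF-YC10 at 1.07 and 0.61. NF-YC6 stood at −1.44 and −1.01, and the sign turned with median scaling, to 0.12 and 0.53, and in the authors' values, to 0.11 and 0.44.

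This comparison crosses arrays, and the normal growth array stood apart in signal. Median scaling of each channel moved the median of all genes by 0.82 in wild type and 0.84 in AhNF-YC-OE, and the authors' values by 0.82 and 0.88. The main scaling matches the whole distribution of intensity between arrays, not its median alone. The changes given above are relative to that distribution, so median scaling can move a gene by another amount than the median. The split became 11917 higher and 2368 lower in wild type and 11823 and 2181 in AhNF-YC-OE with median scaling. In the authors' values it was 12018 and 2224, and 12138 and 2097. Among genes brighter than 95% of empty spots it was 1354 and 2577 in wild type and 946 and 2319 in AhNF-YC-OE, with the median moved by −0.17 and −0.15. This filter passed 46.1% of gene spots on the normal growth array and 85.1% on the water stress array. It thus selects mainly genes bright under normal growth, which by itself shifts the split downward. The changes of both genotypes correlated with r of 0.956 across genes, which share their spots and arrays.

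Recovery over water stress within each genotype compares 1 array with another. Rewatering, the length of stress (8 against 5 days, per the labels) and the array differ together in it. Nuclear photosynthesis genes stood lower as a group, with a median of −0.26 in wild type and −0.41 in AhNF-YC-OE, at the 0.40th and 0.0th percentile of random lists. Of 41 members, 6 were at least 2-fold lower in wild type and 8 in AhNF-YC-OE, with 0 higher. RBCS2B, a Rubisco small subunit, stood at −1.97 and −1.99, and PSBP1, of photosystem II, at −1.45 and −1.40. PETE2 stood at −1.26 in AhNF-YC-OE. LHCB1.5, a light-harvesting protein, stood at −1.04 and −1.10, but on the last of its spots alone at 0.41 and 0.36. Among members above the median intensity of both arrays the list median was 0.01 in wild type and −0.07 in AhNF-YC-OE.

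Seed storage genes, fixed as markers of another organ, stood higher, with medians of 0.70 in wild type and 0.55 in AhNF-YC-OE over 7 members, at the 100.0th and 99.99th percentile. The random lists were matched on intensity only and do not keep the place of the spots on the slide. OLEO1, an oleosin, stood at 1.20 and 1.30, with 0.56 and 0.67 in the authors' values, and the albumin genes SESA4 at 0.75 and 0.55, SESA3 at 0.73 and 0.63, and SESA2 at 0.70 and 0.59. In the authors' values the medians were 0.07 and 0.08, with SESA2 at −0.20 and SESA3 at −0.19 in AhNF-YC-OE. Flowering time and clock genes had a median of −0.20 in AhNF-YC-OE, at the 2.23rd percentile, and of 0.03 in wild type. Under water stress over normal growth the same list had 0.45 in AhNF-YC-OE, at the 98.5th percentile, and 0.27 in wild type. That value of 0.45 turned to −0.05 among members above the median intensity and to −0.11 among those brighter than 95% of empty spots.

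The dehydrin gene COR47 was −1.11 in wild type and −1.34 in AhNF-YC-OE in recovery over water stress, and KIN2, a cold and ABA-responsive gene, −1.24 and −1.35. RAB18 stood at −0.89 and −0.69 and NCED3 at −0.23 and −0.39. RD29A stood at 0.08 and −0.27, ERD5 at 0.31 and 0.18, the latter at −0.01 with median scaling. LTI30 at 0.08 and 0.09 turned to −0.16 and −0.13 with median scaling. RD29B at 0.04 and 0.05, RD20 at −0.12 and −0.04, and P5CS1 at −0.05 and −0.01 were near 0, with RD29B at −0.02 after median scaling and RD20 at 0.08 and P5CS1 at 0.06 after median centring, all in wild type.

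In recovery over water stress, 1029 genes were at least 2-fold higher and 1046 lower in wild type, and 812 and 958 in AhNF-YC-OE. The highest named genes were FC2 (AT4G24740) at 4.52 in wild type and 3.52 in AhNF-YC-OE, AGL78 at 3.01 and 3.26, FRO1 (AT5G67590) at 2.94 and 2.82, and GTF2H2 at 2.77 and 2.42. FC2 stood at −0.07 and −0.16 on the first of its spots alone. In wild type CYP71A14 stood at 3.56 and SWI2 at 2.90, and in AhNF-YC-OE PRT6 at 2.72 and CF9 at 2.46. The lowest named genes were SIP1 at −9.84 and −8.15, DAR6 at −3.14 and −2.90, the glucosyltransferase gene UGT84A3 at −2.92 and −2.74, CO, a regulator of flowering, at −2.42 and −2.27, and CSLG3 at −2.41 and −2.24. SIP1 was also the highest named gene of the genotype ratio in recovery, an array on which empty spots had a median log2 ratio of 0.95. CYP71B7 at −2.48 in wild type and the expansin gene EXPA17 at −2.28 in AhNF-YC-OE were also among them. The median of all genes moved by −0.16 with median scaling in both genotypes and by −0.20 in the authors' values. The split became 686 higher and 1550 lower in wild type and 606 and 1310 in AhNF-YC-OE with median scaling, 578 and 2798, and 564 and 2577, in the authors' values, and 663 and 1085 in wild type against 1299 and 1185 in AhNF-YC-OE with median centring.

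The gene lists fixed in advance stood near 0 between genotypes. Under normal growth the 24 medians ran from −0.13 to 0.09 and none lay outside the middle range of random lists. Under water stress they ran from −0.23 to 0.15 and in recovery from −0.15 to 0.14, with 1 list outside on each array, where chance gives 1.2. Under water stress it was the 6 phosphate starvation genes, with a median of −0.23 at the 1.93rd percentile. Their members were PS2 at −0.59, MGD3 at −0.37, SPX3 at −0.24, SPX1 at −0.23, SQD2 at −0.09 and PHT1;1 at 0.52, and median centring turned the median to 0.19. With genes brighter than 95% of empty spots it lay at the 2.62th percentile, inside the middle range. In recovery it was the 10 NF-YA genes, with a median of 0.14 at the 98.9th percentile, and −0.14 among members above the median intensity. That list lay inside the middle range with median centring (0.07), print-tip loess (0.06), the authors' values (0.05), the mean of the probes (0.10) and genes brighter than 95% of empty spots (0.13). The drought and ABA-responsive list had −0.01, 0.01 and −0.02 in the order of the arrays, and median centring gave 0.17, 0.44 and 0.22. NF-YB genes had 0.06, 0.03 and −0.04, with −0.02 for the second in the authors' values and 0.65 for the last after median centring, NF-YC genes 0.09, 0.06 and −0.00, and aquaporins 0.03, 0.15 and 0.06, the last turned to −0.05, −0.27 and −0.14 by median centring. Neither difference of ratios had a list outside.

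The other lists lay inside the middle range on the water stress array. ABA synthesis and signalling stood at 0.01, nuclear photosynthesis at 0.04, flowering time and clock at 0.08, jasmonate at 0.04, and salicylic acid and pathogen defence at 0.08. Heat shock genes stood at 0.07, endoplasmic reticulum folding at −0.10, antioxidant genes at −0.05, senescence at −0.06, cell wall genes at 0.03, flavonoid genes at −0.03, glucosinolate genes at −0.06 and cell division genes at −0.03. The lists made from words of the annotation stood at −0.08 for 9 ribosomal protein genes and 0.03 for 20 histone genes. Markers of other cell types stood at −0.06 for guard cells, −0.01 for floral organs and −0.08 for seed storage, and median centring turned the last to 0.52. The photosynthesis, jasmonate, ABA and heat shock medians had the same direction with plain subtraction, median centring, print-tip loess and the authors' values, and those of the antioxidant, flavonoid, glucosinolate, cell wall, cell division and ribosomal lists turned with median centring. Trichome and vascular markers had 4 measured members: GL1 at −0.36, GL2 at −0.14, SUC2 at −0.69 and APL at −0.10.

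**Figure D4:**
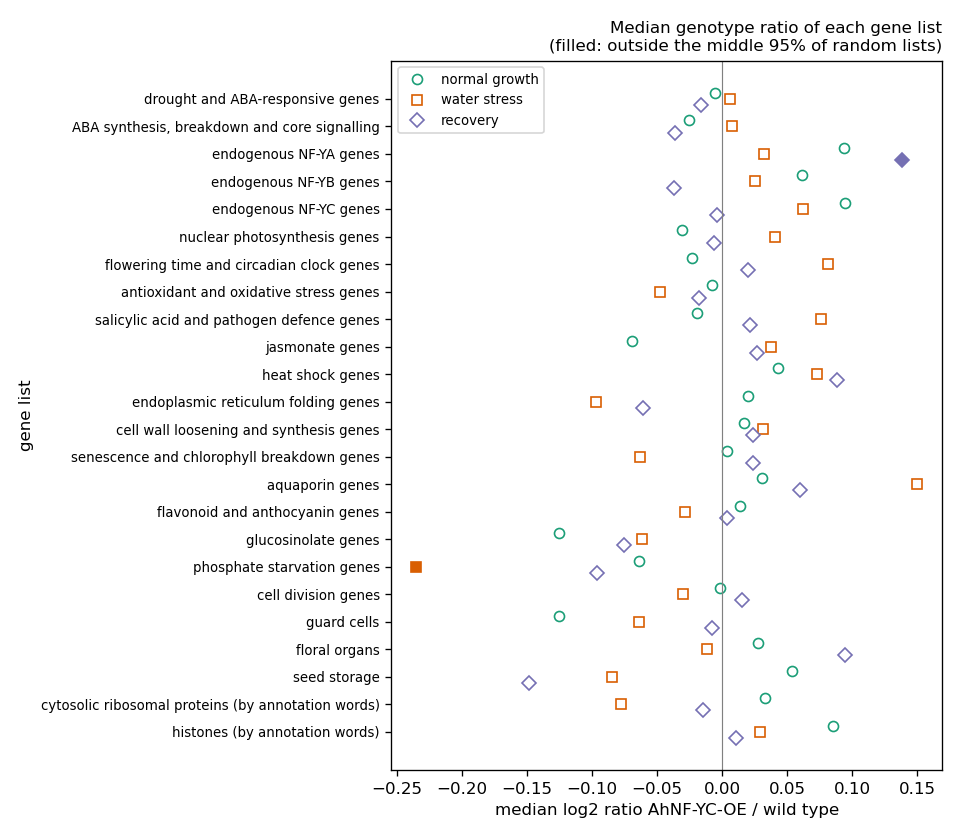
Median log2 ratio of AhNF-YC-OE over wild type (horizontal axis) of the 24 gene lists with at least 5 measured members (vertical axis), with 1 symbol per array and filled symbols outside the middle 95% of random lists. The filled symbols are phosphate starvation genes at −0.23 under water stress, which median centring turned to 0.19, and NF-YA genes at 0.14 in recovery, which turned to −0.14 among members above the median intensity.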

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

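The tests of the dye effect, of the intensity trend and of the place on the slide were planned before their results were seen, and the tests of the 3 explanations for unlike spots of one gene, of a shared genotype difference and of chromosome 1 genes at the border of the chromosomes were chosen only after the result was seen. Control spots named alien, a name for probes without a plant target, gave signal in data outside the gene comparisons: their median lay at percentile 56.25 of library gene spots under normal growth, 76.84 under water stress and 70.66 in recovery. Whether matching RNA was added to the samples is not given in the sources used here.

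Spots annotated to the same transcript shared little of their signal level, with correlations across spots of 0.042, 0.049 and 0.074. A shift or turn of the whole annotation grid is argued against by the highest correlation over 28921 flips, turns and shifts, 0.141, which is above the 0.0544 of the deposited placement but short of the 0.3 asked of a right placement. It is also argued against by the 510 empty spots, whose median lay at percentile 1.24 or below on each array. Under normal growth this was less clear. The 300 empty spots in rows 1 to 24 of the blocks lay at percentile 8.02 there by their median. The 95th percentile of all empty spots, 5617 above background in wild type, exceeded the median gene spot of 4208. Gene names that belong to none of the library spots are argued against by spots of one locus on one plate, whose lowest correlation over the arrays, 0.114, lay above the highest of the shuffles. Signal that does not depend on the transcript stays open, since alien spots lay at percentile 56.25 or above, and added RNA and unspecific signal cannot be told apart. No biological explanation was tested.

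The genotype ratios of water stress and recovery went together across genes, with a correlation of 0.671. Loess had already been applied to these ratios. An intensity trend left after it is argued against by the median correlation within 10 classes of intensity, 0.664. The place on the slide was not tested for this correlation. A dye effect of each spot goes with the correlation of 0.744 across 22 alien and atc control features, and of 0.897 across the 10 alien features alone. Between normal growth and these arrays the 22 features correlated at 0.120 and 0.0987, and the 10 alien features at 0.306 and 0.243. These are too few to say whether such an effect is alike on all 3 arrays. A genotype difference that stressed and rewatered plants share stays open: spots of one transcript correlated at 0.154 in their mean ratio. That test cannot decide where names and signal levels go together only weakly.

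The genes lower in AhNF-YC-OE under water stress and in recovery lay mostly on chromosome 1, 67 of 88 and 74 of 100. The place on the slide goes with the adjacent spots that were not lower themselves in recovery, whose median log2 ratio was −0.234, against −0.0389 for all chromosome 1 spots. A genotype difference of genes on chromosome 1 wherever they are printed stays open: the share of lower spots in recovery was 9.63 times as high in the last full block rows of chromosome 1 as in the first of chromosome 2 (95% interval 2.99 to 49.4), and 1.97 times as high in rows 1 to 3 as in rows 4 to 6 of chromosome 1 (1.24 to 3.19). Under water stress these ratios were 29.9 (4.97 to 1219) and 1.40 (0.856 to 2.32), which meets what this explanation asks of them, while recovery does not. The library is printed largely in chromosome order, so this comparison of rows cannot tell the printing row and the chromosome apart. Some spots lie out of that order, with chromosome 1 found from row 1 to row 24, and they were not compared on their own. With loess within print-tip blocks 53 genes were lower in recovery, and 55 of the 114 genes past the threshold kept their call, among them RHA1A on chromosome 4.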

How the results depend on the processing

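The alternative of genes brighter than 95% of empty spots was chosen only after the data were seen, and all others were fixed before the data were examined. Of 138 counts recomputed, 90 stayed within 1.5 times the main count and 48 did not. A count can stay while its genes change. Under normal growth the authors' values called 25 genes against 26, and 10 were the same. In recovery print-tip loess called 80 genes against 114, and 55 were the same. The first spot, the last spot and the mean of the probes could change little, since 1926 of 26017 loci have more than 1 spot. RHA1A kept its direction and its side of the threshold on all 3 arrays wherever it was tested, from −1.83 to −2.90. It has 1 spot, so the first spot, the last spot and the mean of the probes could not change it. A dye bias of that spot would enter each array alike. Signal over background, from 14.9 to 85.9, limits what dim genes can show. On each array, the genes that passed either intensity filter kept their calls, so the calls lost there were those of the dimmer genes removed. The window rule sets its limit by the spread of genes of like intensity, not by fold. Median centring leaves out the loess step, so any trend of the ratio over intensity stays in its counts. Whether that trend alone moved them was not tested. For the other moved counts the cause was not tested.

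Under normal growth, with 26 genes past the threshold, plain subtraction gave 57, median centring 430, print-tip loess 15 and the window rule 1215. Under water stress, with 216, plain subtraction gave 723, median centring 5439, the authors' normalized values 383, genes above the array's median intensity 2, the window rule 1201 and genes brighter than 95% of empty spots 91. In recovery, with 114, plain subtraction gave 455, median centring 540, the authors' values 251, genes above the median intensity 1 and the window rule 1219. Over all 3 arrays, with 2, plain subtraction gave 9, median centring 95, print-tip loess 1, genes above the median intensity 0, the window rule 62 and genes brighter than empty spots 0.

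For water stress minus normal growth, with 208, plain subtraction gave 700, median centring 2958, the authors' values 382, genes above the median intensity 34, the window rule 1249 and genes brighter than empty spots 33. For recovery minus normal growth, with 86, the same alternatives gave 409, 306, 230, 13, 1236 and 18.

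For water stress over normal growth in wild type, with 7904, the authors' values gave 14242, genes above the median intensity 3154, the window rule 1169, median scaling 14285 and genes brighter than empty spots 3931. In AhNF-YC-OE, with 6736, the same alternatives gave 14235, 2515, 1185, 14004 and 3265. For recovery over water stress in wild type, with 2075, the authors' values gave 3376, genes above the median intensity 740 and the window rule 1150. In AhNF-YC-OE, with 1770, the authors' values gave 3141 and genes above the median intensity 663.

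Of named gene values past 2-fold and list medians outside the middle range, 18 turned direction; values nearer 0 that turned are given in the report and not counted here. The cause was not tested. The phosphate starvation median under water stress became 0.19 with median centring, and the NF-YA median in recovery −0.14 above the median intensity. The flowering and clock median of AhNF-YC-OE, water stress over normal growth, became −0.054 above the median intensity and −0.11 among genes brighter than empty spots. The photosynthesis median of wild type, recovery over water stress, became 0.0109 above the median intensity. In the authors' values SERPIN1 became −0.17 under water stress, and, for water stress minus normal growth, DAF1 −0.60 and scpl38 −0.12. For water stress over normal growth NF-YC6 became 0.11 in wild type and 0.44 in AhNF-YC-OE in the authors' values, and 0.12 and 0.53 with median scaling. For recovery over water stress, FC2 (AT4G24740) became −0.067 in wild type and −0.16 in AhNF-YC-OE on its first spot. LHCB1.5 became 0.28 and 0.13 above the median intensity, and 0.41 and 0.36 on its last spot.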

Other observations

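The lists given here were fixed in advance, and the single genes and the spots of one gene were chosen only after their values were seen. Guard cell markers had a median of 0.38 in wild type and 0.43 in AhNF-YC-OE for recovery over water stress, at the 92.5th and 96.3th percentile of random lists. Antioxidant genes had −0.27 and −0.23, at the 3.25th and 3.69th percentile. Phosphate starvation genes had 0.11 in wild type and 0.38 in AhNF-YC-OE, at the 68.2th and 96.1th percentile. All of these lie within the middle 95% of random lists. The direction of the guard cell and antioxidant medians was the same with each scaling tried, while the phosphate median of wild type was −0.16 in the authors' values.

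Levels on the normal growth array stood apart from those on the other arrays. Across genes, which are not independent replicates, wild-type levels correlated at 0.912 between normal growth and water stress and at 0.974 between water stress and recovery, and AhNF-YC-OE levels at 0.925 and 0.978. The 14 ribosomal protein spots found by words of the annotation lay at the 66.6th, 67.5th and 61.4th percentile of library gene spots by their median. Pseudogene spots lay at the 52.8th, 52.5th and 52.0th, both in the order of the arrays.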
